A study of Mus musculus with 4 samples.

How the data were processed

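The starting values were raw molecule counts per gene and barcode as deposited by the authors, 1 matrix per library, with every barcode of the kit listed and no filtering or normalisation applied before deposition. The counts were read as UMIs because they are whole numbers from a kit with molecular identifiers. The labels give the kit, a full-length immune receptor kit of Singleron, and paired-end 150 base reads on a NovaSeq. The genome build, annotation, aligner and counting program were not given in the sources used here, so gene positions are not stated and genes are identified by the symbol and Ensembl identifier of the deposited gene table. T cell receptor sequences were not part of the deposited matrices. Duplicate symbols, 52 of them, were kept as separate genes, and a symbol was read from its first entry.

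The markers, the gene lists, the rule for named genes, the pairs of libraries, the filters and 18 alternatives were set before the data were examined, and 6 alternatives were added after. Other steps chosen on the data are named as such below.

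Cells were barcodes with at least 300 genes, at most 20% mitochondrial UMIs and at least the larger of 500 UMIs and the inflection point of the library's barcode-rank curve, the steepest fall on log axes between 200 and 5000 UMIs, read on 24 steps. The steepest point with the ends of the range allowed was 214 UMIs in each library, at the lower end, and would have left the 500 UMI floor in force. The steepest interior point was used, 1599 UMIs for chow and 1223 for the others, a reading made after the curves were seen, and the 500 UMI minimum stands among the alternatives. This gave 13295 barcodes for chow, 23644 for salted chow, 19336 for the Western diet and 22300 for the salted Western diet. Of these, 108, 149, 168 and 35 passed the mitochondrial limit and were removed. Scrublet, run per library with an expected rate of 6%, marked 290, 1373, 925 and 1553 doublets, from 2.20% to 6.98% of a library, which were removed, and 73974 cells remained.

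Counts were normalised to 10000 per cell and log-transformed, 2000 variable genes were chosen per library, and 30 principal components with 15 nearest neighbours fed Leiden clustering at resolution 1 with seed 0, on the 4 libraries together without batch integration. Each cluster took the class with the highest mean log2 ratio of its fixed markers to the median cluster. It stayed unnamed when fewer than 3 of those markers reached 10 CPM and 2-fold over the other cells, when its 10 leading genes held more markers of another class, when it was shallow without an own marker among them, or when 3 of 6 genes of myeloid progenitors (Mpo, Elane, Ctsg, Prtn3, Myb, Ms4a3) led it, the last a rule added after the clusters were seen. Markers covered 22 classes with 199 entries, of which 2 symbols, Tcrg-C1 and Ahsp, were missing. Examples are Clec4f, Vsig4 and C1qa for Kupffer cells, Gpnmb, Trem2 and Ccr2 for monocyte-derived macrophages, Ly6c2 and Plac8 for monocytes, S100a8, Retnlg, Ngp and Camp for neutrophils, Xcr1 for type 1 and Cd209a for type 2 dendritic cells, Siglech for plasmacytoid dendritic cells, Cd3e for T cells, Ncr1 for natural killer cells, Trdc and Il7r for the gamma-delta T or innate lymphoid class, Cd79a for B cells and Jchain for plasma cells.

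The doubtful clusters were those named without any of their own markers among the 10 leading genes, or named neutrophil with B cells as the next best class, and there were 6 of them (2 of neutrophils, 2 of monocytes, 1 of type 1 dendritic cells and 1 of T cells). Clusters that took most of their cells from 1 library were kept, since with 1 library per diet the library and the diet coincide.

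Shares were taken over immune-class cells with exact Clopper-Pearson intervals. Share ratios carry intervals from a normal approximation on the log ratio. UMIs were summed per class and library and scaled to CPM, and levels carry exact Poisson intervals and ratios of levels exact conditional intervals. Log2 folds were formed on CPM plus 10 for classes with at least 50 cells in both libraries. Empty barcodes, with 10 to 100 UMIs, numbered 655259, 696174, 688133 and 694800 and held 36228121, 34490243, 35756435 and 35530406 UMIs for chow, salted chow, the Western diet and the salted Western diet.

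The 27 fixed lists covered the urea cycle, polyamines and hypusination, de novo lipogenesis, fructose, cholesterol and bile acid metabolism, fatty acid oxidation with PPARA targets, gluconeogenesis, the acute phase, pericentral and periportal zones, lipid-associated and resident macrophages, inflammatory cytokines with NF-kB, type I interferon, MHC class II, fibrosis, sinusoidal identity, capillarisation, T cell activation and exhaustion, the IL-17 axis, the osmotic response, endoplasmic reticulum stress, NRF2, oxidative phosphorylation, proliferation and dissociation stress. They held 304 entries, of which the symbol Mx1 was missing. A member was measured at 10 CPM or more in 1 of the 2 libraries, a list with at least 3 such members got a median with an interval from 400 Poisson redraws of its counts, and its percentile came from 10000 random lists matched in 20 bins of mean level. Resident Kupffer and lipid-associated lists share members with the class markers, as do some lists in other classes. Of 24 list medians recomputed without those members, 7 moved beyond counting error. Of the 6 medians past 1.5-fold among them, 4 stayed past it. The value of the resident list on salted chow is given below. List members and markers at no count in 1 library were also set to 3 counts.

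Named genes were, for each pair and each of the 4 comparable classes with the most cells in the smaller library, the 3 with the highest and the 3 with the lowest log2 fold. They needed at least 50 CPM and 30 UMIs in the higher library and a level above the empty barcodes there. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor segment genes, Xist and Malat1 were left out. Up to 4 members of each list with the largest folds and Cps1, Ass1, Arg1, Otc, Asl, Eif5a, Dhps and Dohh were added. Predicted genes without a settled name that met the rule are not discussed, and list members outside the rule, along with S100a8 and Alb in the empty barcodes, were named after their values were seen.

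Free RNA was subtracted, as an alternative, in proportion to 7 secreted-protein genes of hepatocytes in each class, up to a limit of 50% of the class sum. Among the immune classes Kupffer cells reached this limit on salted chow and the Western diet, and neutrophils and B cells on the Western diet. Subtracted values for those classes are set by the limit. Unnamed cells held 49862 UMIs of the secreted-protein genes on the salted Western diet and 895 on the Western diet, so this background was not of hepatocytes alone. For monocytes and macrophages a second subtraction, chosen after the data were seen, scaled it by neutrophil marker genes.

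In a self-test, counts of monocytes were redrawn with 200 genes changed by 1.5-fold, 2-fold or 4-fold. All of the changed genes kept their direction in each of the 4 pairs, between 90.9% and 98.5% of their true folds lay inside the counting interval, and a raised list of 12 genes reached the percentile of 100. Among 40 unchanged lists percentiles ran from 9.86 to 96.1 in the first pair and from 0.150 to 99.3 in the pair of the salted Western diet with chow, so an unchanged list can come near the ends. The redraws held counting error alone and do not show how often lists in real libraries do so.

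The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for the trimmed-mean factors.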

Results

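Single-cell RNA sequencing was done on liver cells of male C57BL/6J mice kept for 16 weeks on 1 of 4 diets. The control mice ate normal chow and drank tap water, and the salted chow group ate chow with 8% salt. The Western diet group ate a Western diet and drank water with 15% fructose, a regimen that produces steatohepatitis, that is, a fatty liver with inflammation. The salted Western diet group had the same drinking water and a Western diet with 8% salt. Dissociated liver was spun for 1 min at 100 g to enrich immune cells, and 1 library was made per diet with a full-length kit that also captures T cell receptors. The labels do not say how many mice went into each library. The title of the series names salt added to a diet that produces steatohepatitis, the urea cycle of the liver and hypusination of EIF5A, the step that turns this translation factor into its active form.

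The unique molecular identifiers (UMIs) of a library summed to 193290209 for chow, 218889809 for salted chow, 210176277 for the Western diet and 215846426 for the salted Western diet, over 28292, 26676, 26934 and 26657 genes with a UMI. After the filters, 12897, 22122, 18243 and 20712 cells remained in that order, with median depths of 3904, 3308, 4044 and 3764 UMIs and medians of 1538, 1303, 1635 and 1564 genes per cell. The UMI minimum for a cell was 1599 in the chow library and 1223 in each of the other 3. Barcodes with 10 to 100 UMIs, which hold RNA that floated free of cells, served as the background of each library and are called empty barcodes here.

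The cells formed 39 clusters, of which 34 were named from fixed marker genes and 5 stayed unnamed. Leucocytes fell into 12 classes, with 12279, 20641, 18151 and 19847 cells in the order chow, salted chow, Western diet and salted Western diet, and shares below are of these immune-class cells. No cluster met the naming rule for hepatocytes, vascular endothelium, stellate cells, fibroblasts, cholangiocytes, mature dendritic cells, basophils or platelets, though unnamed clusters carried some duct and platelet genes. Cluster 21 scored highest for basophil or mast cells and stayed unnamed only through the myeloid progenitor rule, added after the clusters were seen. Sinusoidal endothelial cells numbered 152, 32, 17 and 41, and erythroid cells, which were mixed with liver RNA, 187, 19, 8 and 81. Because the spin and the UMI minimum set which cells were captured, a share describes the captured cells, not the liver. With 1 library per diet there was no replicate of any diet, so no test, p-value, standard error or count of changed genes is given. Values in parentheses after a share, a level in counts per 1000000 (CPM) or a ratio are 95% intervals for counting error only, exact binomial for shares and exact Poisson for levels. Folds of genes are log2 of CPM plus 10, and a list is described by the median over its measured members and by its percentile among 10000 random lists matched on level, a description of these libraries alone.

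On the Western diet, the salted library held a larger share of Kupffer cells, the resident macrophages of the liver sinusoids, and its neutrophils and monocytes carried less inflammatory cytokine RNA. This pair of libraries addresses what salt adds to a diet that produces steatohepatitis. Kupffer cells were 9.31% (8.91 to 9.72) of immune-class cells with salt and 1.55% (1.37 to 1.74) without, a ratio of 6.01 (5.31 to 6.81). The fixed list of inflammatory cytokine and NF-kB genes was lower in neutrophils, with a median log2 fold of −1.65 (−1.69 to −1.56), 11 of 11 measured members at least 1.5-fold lower and a percentile of 0. The type I interferon list, made of antiviral response genes, was higher in monocytes by 0.56 (0.52 to 0.60), with 5 of 12 members at least 1.5-fold higher and a percentile of 100.

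Among the other myeloid cells, monocyte-derived macrophages were 8.15% (7.77 to 8.54) with salt and 16.9% (16.4 to 17.5) without, a ratio of 0.482 (0.456 to 0.510). Monocytes had a ratio of 0.800 (0.771 to 0.829) and neutrophils of 0.644 (0.618 to 0.671). Type 1 conventional dendritic cells, which present antigen to CD8 T cells, stood at 5.48% with salt and 2.69% without, a ratio of 2.03 (1.83 to 2.26), whereas type 2 cells had a ratio of 0.999 (0.916 to 1.09). Plasmacytoid dendritic cells, the main makers of type I interferon, had a ratio of 1.45 (1.11 to 1.90). Among lymphocytes, B cells were 19.6% with salt and 6.75% without, a ratio of 2.91 (2.74 to 3.09). The gamma-delta T or innate lymphoid class held 185 cells with salt and 36 without, a ratio of 4.70 (3.29 to 6.71). T cells had a ratio of 0.819 (0.774 to 0.867), natural killer cells of 1.08 (0.947 to 1.24) and plasma cells of 1.35 (1.12 to 1.63). The neutrophils of the 2 libraries lay mostly in different clusters. In the Western diet library 60.0% of them were in cluster 8, which took 82.5% of its cells from that library and was led by Cxcl2, Acod1 and Ccrl2, with no neutrophil marker among its 10 leading genes. In the salted library 82.8% were in cluster 5. Of the monocytes, 39.5% lay in cluster 11 without salt, which took 82.7% of its cells from the Western diet library, and 72.6% lay in cluster 0 with salt.

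**Figure D1:**
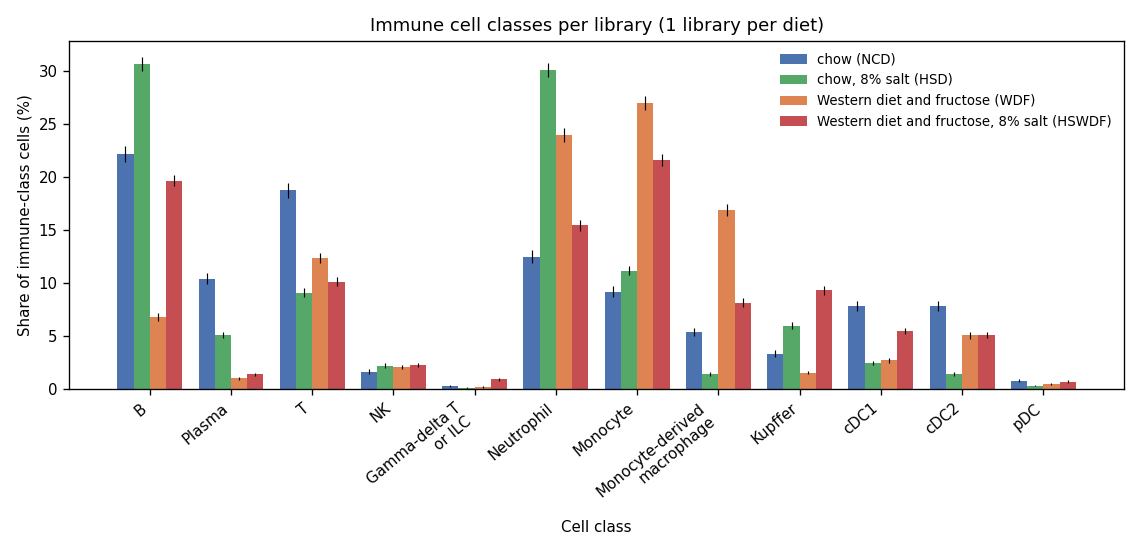
Share of each immune cell class, in percent of immune-class cells (vertical axis), in the 4 libraries, with 1 library per diet and exact binomial 95% intervals for counting error as black lines. Kupffer cells stood at 9.31% on the salted Western diet and 1.55% on the Western diet, and neutrophils at 30.1% on salted chow and 12.5% on chow.

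Inflammatory transcripts were lower with salt in neutrophils and monocytes. In neutrophils Cxcl2 (ENSMUSG00000058427), a chemokine that attracts further neutrophils, was at 441 CPM (425 to 457) with salt and 2906 CPM (2874 to 2939) without, a log2 fold of −2.69. Acod1 (ENSMUSG00000022126), the enzyme that makes itaconate in activated myeloid cells, was at 449 and 2940 CPM, and Cd14 (ENSMUSG00000051439), a co-receptor for bacterial lipopolysaccharide, at 195.2 and 1258 CPM. The chemokines Ccl4 and Ccl3 had log2 folds of −2.62 and −1.65, Tnf of −1.67, the prostaglandin synthase gene Ptgs2 of −1.86 and Il1b of −0.63. The feedback inhibitors of NF-kB Tnfaip3 and Nfkbia were lower as well, at −1.75 and −1.54. The same list was lower in monocytes, at a median of −1.52 (−1.57 to −1.47) with 10 of 10 members at least 1.5-fold lower, and there Cd14 (−2.50), Thbs1 (−2.25), which encodes a matrix glycoprotein, and Clec4e (−2.12), a receptor for microbial glycolipids, had the lowest folds under the rule for named genes. Its medians were −0.68 in monocyte-derived macrophages and −0.57 in Kupffer cells, with 6 of 9 and 5 of 10 members at least 1.5-fold lower, but 0.17 and 1.10 once free RNA was subtracted. The share taken off was uneven, at 36.8% without salt and 12.3% with it in the macrophages. In Kupffer cells it was at its limit of 50% without salt and at 14.9% with it. Scaled by neutrophil markers, the macrophage shares were 11.7% and 13.5%. RNA of these genes was also more abundant in the empty barcodes of the Western diet library, where Cxcl2 stood at 374 CPM against 35.3 in the salted library. The fixed dissociation list, stress genes induced by tissue handling, was itself lower with salt, at −0.23 in neutrophils, −0.47 in monocytes and −0.39 in T cells.

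**Figure D2:**
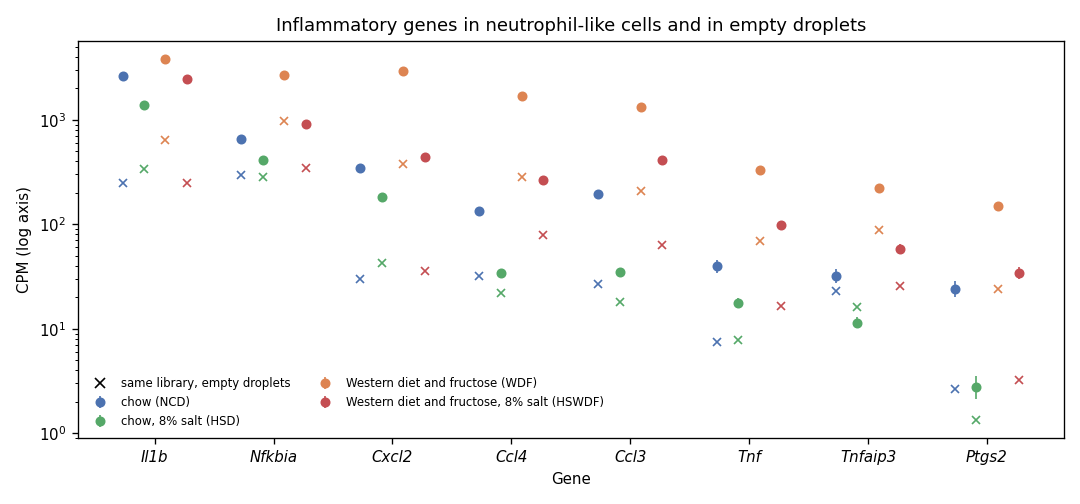
Levels of 8 members of the inflammatory list in neutrophils (circles, with exact Poisson 95% intervals for counting error) and in the empty barcodes of the same library (crosses), in CPM on a log axis, for the 4 libraries. Cxcl2 in neutrophils stood at 2906 CPM on the Western diet and at 441 on the salted Western diet.

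The list medians of oxidative and protein-folding stress genes were also lower with salt in the classes given here. The list of NRF2 targets, which guard cells against oxidants, had a median of −1.14 in neutrophils, with 6 of 7 members at least 1.5-fold lower, among them Srxn1 (−1.92), Txnrd1 (−1.73) and Hmox1 (−1.17). The endoplasmic reticulum stress list was at −0.57 in monocytes, with the chaperone Hspa5 at 480 CPM with salt and 1028 without, and Herpud1 at −0.83. It was at −0.32 in monocyte-derived macrophages and −0.29 in neutrophils.

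Interferon-response genes moved the other way. In monocytes Ifit3 (ENSMUSG00000074896) was at 68.4 CPM (65.3 to 71.5) with salt and 23.7 CPM (22.2 to 25.3) without, and Oasl2 (0.86), Zbp1 (0.69) and Irf7 (0.61), the transcription factor that amplifies interferon production, were higher too. The nucleic acid sensor Ifi213 (1.15) and the glucocorticoid-induced Tsc22d3 (1.003) completed the highest folds in monocytes. Ifit3 RNA was also more abundant in the empty barcodes with salt, at 57.9 CPM against 24.8. In neutrophils the list median was 0.58, with Ifit3 at 1.74, Ifit3b at 1.40 and Stfa1, a cysteine protease inhibitor of neutrophils, at 2.09. Plasmacytoid dendritic cells had a median of 1.03 with 10 of 12 members at least 1.5-fold higher, among them Ifi44 (1.62) and Zbp1 (1.16). The medians were 0.61 in natural killer cells, 0.48 and 0.21 in type 1 and type 2 dendritic cells, 0.46 in monocyte-derived macrophages, 0.25 in B cells, 0.23 in Kupffer cells, 0.22 in T cells and 0.11 in plasma cells. Scaling by trimmed means shifted the median of all genes in neutrophils by −0.24, from 0.19, and left their interferon median at 0.29. A member with no count in 1 library was set to 3 counts in 7 list medians of small classes, which left each of those medians where it was.

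In Kupffer cells the list of resident identity genes was higher with salt, at 0.72 (0.67 to 0.78) with 8 of 11 members at least 1.5-fold higher. Of its 11 members 6 also serve as class markers, and the median without them is not given for this pair. The mix of Kupffer cells differed, with 32.1% in the cluster led by Clec4f with salt and 21.7% without. The cluster led by C1q genes and Ms4a7 held 59.7% and 70.1%. In the Clec4f-led cluster alone, 1 of 7 Kupffer list medians past 1.5-fold, over all pairs and lists, stayed past it. A higher resident list in the class may thus reflect its mix of clusters. Clec4f (ENSMUSG00000014542), a lectin receptor of resident Kupffer cells, was at 2639 CPM (2612 to 2666) with salt and 1389 CPM (1343 to 1435) without, the scavenger receptors Marco and Cd163 had log2 folds of 2.03 and 0.76, and Timd4, which binds dying cells, 0.79. Lipid-associated macrophage genes, which mark macrophages that clear lipid and dead cells, had a median of −0.41 in Kupffer cells, with 1 of 13 measured members higher and 4 lower by at least 1.5-fold. There Gpnmb (−1.47), the elastase Mmp12 (−2.23), the lipid carrier Fabp5 (−1.58) and the lipoprotein lipase Lpl (−0.85) were lower, and Spp1 (0.69), at a level under that of the empty barcodes, was higher. Monocyte-derived macrophages had a median of −0.36 for this list and 0.62 for the resident list, with Gpnmb at −0.10, Spp1 at 0.01 and Trem2 at 0.35. In these macrophages Spic, a regulator of iron-recycling macrophages, was at −1.35, the haem-degrading Hmox1 at −1.12 and Ralgds at −1.10, while the heat shock gene Hspa1a (1.48), Ifit3 (1.17) and the junction gene F11r (1.07) were higher. A common UMI minimum gave folds of 2.30 for Hspa1a and 1.68 for F11r. The antigen presentation (MHC class II) list stayed between −0.17 in monocyte-derived macrophages and 0.17 in type 2 dendritic cells.

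T cells of the salted library carried less RNA of the activation and exhaustion list, at −0.39 (−0.44 to −0.36) with 4 of 14 members at least 1.5-fold lower. These were the chemokine Ccl5 (−0.93), the granzymes Gzmk (−0.81) and Gzmb (−0.63) and the death ligand Fasl (−0.60). The dissociation list was at −0.39 in the same T cells, and their mix differed, with 34.3% in cluster 6 with salt and 57.8% without. The chemokine Ccl1 was at 74.9 CPM with salt and 3.31 without, the receptors Klra7 and Klra9 had log2 folds of 1.11 and 1.06, and the heat shock gene Hsph1 of −1.05. The list median in natural killer cells was 0.04 and its mean −0.09. Il17a was under 1.2 CPM in T cells of each library. That level does not describe the whole IL-17 axis list, whose median is not given for this pair. The gamma-delta T or innate lymphoid class had too few cells for list values. The proliferation list was at 0.51 in T cells, 0.55 in neutrophils, 0.37 in B cells and −0.16 in Kupffer cells.

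The urea cycle and hypusination genes that reached 10 CPM, the themes of the series, stayed within 1.5-fold between the 2 libraries in the material and classes given here. Without hepatocytes, liver genes were read in the empty barcodes, where 3 of the 8 urea cycle genes reached 10 CPM and had a median of −0.14. Genes of hepatocytes moved unevenly in the same barcodes, with ratios of 15.9 for Alb, 15.8 for Ttr, 4.56 for Apoa1 and 0.937 for Mup3, so these levels do not describe the urea cycle of hepatocytes. Unnamed cluster 23 also carried Alb, at 5461 CPM, and Ttr, at 2728 CPM, and held 637 cells with salt and 15 without. Alb and Ttr therefore cannot be read as RNA of hepatocytes alone, in this pair or the others. Ass1 (ENSMUSG00000076441), which joins citrulline and aspartate, was at 72.1 CPM with salt and 90.3 without, and Asl, the next enzyme, at 25.4 and 28.9 CPM. Cps1, the entry enzyme, had 35 UMIs with salt and 6 without, a ratio of 5.87 (2.44 to 17.1) at levels under 1 CPM, and Otc and Arg1 were at 0.225 and 4.08 CPM with salt. In monocyte-derived macrophages Ass1 stood at 211 CPM with salt and 166 without, and Arg1 at 2.31 and 2.65 CPM. Eif5a (ENSMUSG00000078812) was at 400 and 416 CPM in monocytes, 325 and 343 CPM in Kupffer cells and 442 and 411 CPM in T cells. Dhps and Dohh, the enzymes that make hypusine on EIF5A, were at 29.3 and 34.0 CPM in monocytes with salt and at 29.3 and 37.2 without. The polyamine and hypusination list had medians of −0.05 in monocytes, −0.04 in monocyte-derived macrophages, 0.04 in Kupffer cells and 0.05 in T cells. Its median in neutrophils was 0.26, and −0.10 when scaled by trimmed means. RNA levels do not show the modification of the protein. The osmotic and salt response list was at −0.27 in T cells and −0.08 in monocytes, and oxidative phosphorylation at 0.35 in neutrophils, or 0.03 when scaled by trimmed means.

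Other genes of liver metabolism were also read in the empty barcodes. There immune cell genes stood far above albumin, with Lyz2 at 15577 CPM and Cd74 at 9270 CPM in the Western diet library. With salt they were at 11183 and 10493 CPM. Levels of genes that immune cells also carry therefore do not describe hepatocytes, in this pair or the others. De novo lipogenesis had a median of 0.24 over 6 members, with the fatty acid desaturase Scd1 at 55.1 CPM with salt and 23.3 without. Cholesterol synthesis had a median of 0.12, and fatty acid oxidation with PPARA targets of 0.14. The acute phase list had a median of −0.12 and a mean of 0.11, with members in both directions. Albumin RNA was at 400 CPM with salt and 25.2 without, and Mup3 at 5.35 and 5.71 CPM. The fructose, bile acid, gluconeogenesis, periportal and pericentral lists had at most 2 measured members in this pair and no median. The fibrosis list had no stellate class to be read in, and the sinusoidal identity and capillarisation lists had too few endothelial cells, so these 3 have no value in any comparison.

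With 6 clusters of doubtful identity left out, cluster 8 among them, an alternative chosen after seeing the data, the neutrophil ratio was 1.19, the neutrophil inflammatory and NRF2 medians were −0.55 and −0.15, and the neutrophil folds of Cxcl2, Acod1 and Cd14 were −1.19, −1.59 and −1.47. Members of the inflammatory list such as Cxcl2 led cluster 8, so these values describe the remaining neutrophils alone. Other alternatives gave Kupffer ratios up to 9.98, ratios of monocyte-derived macrophages from 0.261 to 0.762, resident medians in Kupffer cells of 0.02 after free RNA was subtracted (at its limit without salt) and 0.13 with each library clustered alone, and, at resolution 2, a plasmacytoid dendritic cell ratio of 0.976, an interferon median of 0.08 in natural killer cells and a Ccl1 fold of 0.68.

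The Western diet with fructose, compared with chow, came with larger shares of monocytes and monocyte-derived macrophages, smaller shares of Kupffer and plasma cells, and neutrophils rich in inflammatory RNA. This pair sets the disease-inducing diet beside chow. Monocyte-derived macrophages were 16.9% (16.4 to 17.5) on the Western diet and 5.36% (4.97 to 5.77) on chow, a ratio of 3.15 (2.91 to 3.42), and monocytes had a ratio of 2.93 (2.76 to 3.11). The inflammatory list was higher in neutrophils by 2.23 (2.04 to 2.41), with 10 of 11 members at least 1.5-fold higher and a percentile of 100. The lipid-associated macrophage list was higher in monocyte-derived macrophages by 0.73 (0.64 to 0.82), with 9 of 13 members at least 1.5-fold higher and a percentile of 100.

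Kupffer cells stood at 1.55% on the Western diet and 3.31% on chow, a ratio of 0.468 (0.403 to 0.544), and neutrophils had a ratio of 1.92 (1.82 to 2.03). Plasma cells, which secrete antibodies, were 1.02% against 10.4%, a ratio of 0.0985 (0.0846 to 0.115), and B cells had a ratio of 0.305 (0.286 to 0.325). T cells were lower at 0.660 (0.625 to 0.696), type 1 and type 2 dendritic cells at 0.345 (0.310 to 0.384) and 0.648 (0.594 to 0.707), and plasmacytoid dendritic cells at 0.601 (0.450 to 0.801). Natural killer cells had a ratio of 1.26 (1.06 to 1.49) and the gamma-delta T or innate lymphoid class of 0.761 (0.473 to 1.22). In the chow library 69.1% of neutrophils lay in cluster 19, which took 92.0% of its cells from that library, and 90.7% of B cells lay in cluster 9, which took 86.9% from it, while 94.2% of Western diet B cells lay in cluster 4. Cluster 11 held 39.5% of the monocytes on the Western diet and 2.39% on chow, and cluster 0 held 34.4% and 69.6%.

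Neutrophils of the Western diet carried Cxcl2 at 2906 CPM against 346 on chow. The highest folds under the rule for named genes were those of Acod1 (3.85), Ccrl2 (3.63), a decoy receptor that presents chemerin, and Ccl4 (3.55), and Tnf was at 2.79. The lowest were those of the secondary granule genes Ngp (−4.68), Camp (−4.54) and Ltf (−4.36), which neutrophils make while they mature. Proliferation genes were lower in neutrophils too, at −1.84 with 10 of 10 members at least 1.5-fold lower, among them Mki67 (−2.26) and Stmn1 (−2.36). The cluster led by Ngp, Ltf and Camp, high in proliferation markers, held 9.33% of the neutrophils on chow and 0.207% on the Western diet. The proliferation median without it is not given for this pair. NRF2 targets were higher in neutrophils by 1.47, led by Txnrd1 (2.26), Srxn1 (2.22) and Hmox1 (1.84). In monocytes the inflammatory list was higher by 1.70 with 10 of 10 members at least 1.5-fold higher, and it was higher by 1.20 in monocyte-derived macrophages and 0.46 in Kupffer cells, the last at −1.19 once free RNA was subtracted. The share taken off those Kupffer cells was at its limit on the Western diet. The monocyte genes with the highest folds were Spp1 (4.00), which encodes osteopontin, Clec4e (2.87) and Cd14 (2.82), and the lowest were the heat shock gene Hspa1a (−2.18), Tsc22d3 (−1.79) and the lysozyme Lyz1 (−1.60). The endoplasmic reticulum stress list was higher in monocytes by 0.66, with Hspa5 at 1.58. The dissociation list was higher by 0.30 in monocytes, 0.22 in neutrophils and 0.41 in T cells.

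In monocyte-derived macrophages Gpnmb (ENSMUSG00000029816), a glycoprotein of lipid-laden macrophages, was at 295 CPM (288 to 301) on the Western diet and 74.1 CPM (67.2 to 81.5) on chow. Spp1 (1.44), the lysosomal protease Ctsd (0.98), the lipid droplet coat Plin2 (0.97) and Trem2 (0.73), a lipid-sensing receptor, were higher in the same cells. The list was also higher in Kupffer cells, by 0.70 with 9 of 13 members at least 1.5-fold higher, among them Gpnmb (2.04), Mmp12 (1.62) and Lpl (1.40). The resident list was at −0.01 in Kupffer cells, with Marco at −2.21 and Cd163 at −0.86. Kupffer cells had more proliferation RNA, with a median of 1.10 and 9 of 10 members at least 1.5-fold higher, among them Top2a (1.61), whereas B cells (−0.81), monocytes (−0.87) and plasmacytoid dendritic cells (−1.20) had less. Cluster 34, a Kupffer cluster high in proliferation markers, held 8.19% of the Kupffer cells (23 cells) on the Western diet and 0.985% (4 cells) on chow. The Kupffer median therefore does not describe a state of all Kupffer cells.

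Among lymphocytes, T cells of the Western diet had higher levels of the chemokine Ccl4 (2.27), of Eomes (1.11), a transcription factor of effector and memory cells, and of Vps37b (0.98), and lower levels of the cold-inducible Cirbp (−0.90) and the chemokine receptor Ccr6 (−0.85). Their activation list had a median of 0.21. Their IL-17 axis list was at −0.53, with 2 of 5 measured members at least 1.5-fold lower. In B cells Tra2a (0.64) and Id3 (0.55) were higher and Cirbp (−0.97) was lower. The interferon list stayed between −0.23 in monocytes and 0.25 in T cells, and the antigen presentation list between −0.37 in Kupffer cells and −0.04 in type 1 dendritic cells. In the empty barcodes the acute phase list was at −0.85, with 2 of 8 measured members higher and 5 lower, while the hepatocyte genes Alb, Apoa1, Ttr and Mup3 had ratios of 0.0730, 0.0434, 0.149 and 0.181. Saa3 was at 80.1 CPM against 9.14 on chow and the fibrinogen gene Fgb at 3.61 against 36.0. Plin2 was at 299 and 109 CPM. The urea cycle list had a median of 0.09, de novo lipogenesis 0.04, cholesterol synthesis −0.14 with a mean of 0.02, fatty acid oxidation 0.04 and the pericentral list 0.01 with a mean of −0.36, as Cyp2e1 was lower. The polyamine and hypusination list was at 0.15 in Kupffer cells and 0.08 in monocytes, and Eif5a stood at 343 CPM in Kupffer cells against 271 on chow.

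With the 6 doubtful clusters left out, the neutrophil ratio was 0.994, the inflammatory and NRF2 medians of neutrophils were 0.59 and 0.27, and the neutrophil folds of Acod1, Ccrl2, Ccl4, Ngp, Camp and Ltf were 1.57, 1.13, 1.98, −3.30, −3.15 and −3.21. Other alternatives gave ratios of 1.52 to 8.48 for monocyte-derived macrophages, up to 0.806 for Kupffer cells, 1.00 for plasmacytoid dendritic cells and 0.947 for natural killer cells, a macrophage inflammatory median of 0.07 after free RNA was subtracted and lipid-associated median of 0.27 at resolution 2, a Kupffer proliferation median of −0.29 in the Clec4f-led cluster, an acute phase median of 0.81 over members at 50 CPM or more, a monocyte Spp1 fold of 3.17 with a 500 UMI minimum, and Ngp, Camp and Ltf folds of −3.18, −3.08 and −0.61 without the cluster they lead.

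Salt on chow came with a larger share of neutrophils, smaller shares of monocyte-derived macrophages and dendritic cells, and Kupffer cells richer in resident identity genes. This pair shows salt without the disease-inducing diet. Neutrophils were 30.1% (29.4 to 30.7) on salted chow and 12.5% (11.9 to 13.1) on chow, a ratio of 2.41 (2.29 to 2.54), and Kupffer cells had a ratio of 1.81 (1.62 to 2.02). Monocyte-derived macrophages were 1.40% against 5.36%, a ratio of 0.261 (0.228 to 0.299). The resident Kupffer list was higher in Kupffer cells by 1.61 (1.56 to 1.65), with 8 of 11 members at least 1.5-fold higher and a percentile of 100.

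Type 1 and type 2 dendritic cells had ratios of 0.312 (0.281 to 0.347) and 0.183 (0.161 to 0.208), and plasmacytoid dendritic cells of 0.401 (0.293 to 0.547). T cells were at 9.10% against 18.7%, a ratio of 0.486 (0.459 to 0.514), plasma cells had a ratio of 0.491 (0.454 to 0.531) and the gamma-delta T or innate lymphoid class of 0.502 (0.301 to 0.837). B cells had a ratio of 1.38 (1.33 to 1.44), monocytes of 1.21 (1.13 to 1.30) and natural killer cells of 1.35 (1.14 to 1.59). On salted chow 86.8% of neutrophils lay in cluster 3, which took 96.9% of its cells from that library, and 92.7% of B cells in cluster 1, which took 95.5% from it. Of the Kupffer cells on salted chow 81.3% lay in the cluster led by Clec4f, whereas 58.9% of those on chow lay in a cluster led by C1q genes and Ms4a7. The cluster with the most T cells was cluster 10 on salted chow (38.8%) and cluster 6 on chow (43.1%).

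In Kupffer cells Clec4f was at 4934 CPM on salted chow and 1845 on chow, and Folr2 (2.18), a folate receptor of resident macrophages, Cd163 (1.97), Timd4 (1.77), Vsig4 (1.71), a complement receptor, and Marco (1.66) were higher. Lipid-associated genes had a median of −0.16 there, with Mmp12 (−2.36), Cd9 (−1.76), Cd63 (−1.70) and Trem2 (−1.59) lower, and of −0.34 in monocyte-derived macrophages. Antigen presentation genes were lower in Kupffer cells, at −0.76 with 6 of 7 members at least 1.5-fold lower, among them H2-Eb1 (−1.01) and Cd74 (−0.78), and so were 5 of 7 members in plasmacytoid dendritic cells, with the class II activator Ciita at −1.50 and H2-Ab1 at −1.07. Proliferation had a median of 0.57 in T cells, 0.41 in natural killer cells and −0.20 in Kupffer cells.

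Neutrophils on salted chow had less inflammatory RNA, with a median of −0.98 (−1.12 to −0.91) and 9 of 9 members at least 1.5-fold lower. The lowest folds among named genes were those of Thbs1 (−2.73), Ccl3 (−2.19) and Cxcr4 (−1.94), the receptor that holds neutrophils in the marrow, and the highest those of Prok2 (3.02), a secreted prokineticin, Stfa2 (2.49) and Wfdc17 (2.45). The inflammatory medians were −0.34 in monocytes, 0.43 in monocyte-derived macrophages and −0.57 in Kupffer cells. The dissociation list was lower in the same classes, at −0.97 in neutrophils, −0.75 in monocytes and −0.43 in Kupffer cells. Scaling by trimmed means shifted the median of all genes in neutrophils by 0.37, from −0.26, and turned the sign of their interferon (−0.12 to 0.24), oxidative phosphorylation (−0.30 to 0.15) and polyamine (−0.14 to 0.26, with a mean of 0.04 before the scaling) medians. In monocytes the serum amyloid gene Saa3 (4.598), F11r (1.58) and Gpr146 (1.03) were highest, and Hspa1a (−2.28), Lyz1 (−1.46) and the phosphatase Dusp1 (−1.40), the last a member of the dissociation list like Hspa1a, were lowest. The interferon medians were 0.17 in monocytes, 0.59 in monocyte-derived macrophages and −0.18 in natural killer cells.

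T cells on salted chow had less S1pr5 (−2.09), a receptor for leaving tissues, less of the fractalkine receptor Cx3cr1 (−2.05) and less Ccl5 (−1.77), and more of the cell cycle genes Cdkn3 (0.82) and Rrm2 (0.80). Their activation list had a median of −0.23 with 6 of 14 members at least 1.5-fold lower. Their IL-17 axis list had a median of 0.16 and a mean of 0.08, with no measured member past 1.5-fold. In B cells Serpina3g (0.61), Ppp1r21 (0.48) and Mprip (0.41) were higher and Gimap7 (−0.68) and Tagap (−0.58) lower. The osmotic and salt response list had a median of −0.29 in monocytes, −0.35 in natural killer cells and −0.16 in T cells. In the empty barcodes Alb, Apoa1, Ttr and Mup3 had ratios of 0.248, 0.132, 0.408 and 0.377, and the acute phase list at 0.23 with 4 of 9 measured members higher and 4 lower. Fgb was at 8.67 CPM against 36.0, haptoglobin (Hp) at 890 CPM against 326 and the iron-binding Lcn2, also a neutrophil gene, at 2086 against 445. The neutrophil gene S100a8 stood at 28511 CPM in the same barcodes, against 4996 on chow. The urea cycle list had a median of −0.15, with Ass1 at 72.5 CPM against 88.5, and de novo lipogenesis 0.04, cholesterol synthesis −0.15, fatty acid oxidation 0.08 and the pericentral list 0.11 with a mean of −0.25. Eif5a in T cells was at 528 CPM against 459, and in monocytes at 384 against 353.

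The resident Kupffer median was 0.48 without members that are also class markers and 0.52 in the Clec4f-led cluster alone, where the antigen presentation median was 0.20 (0.01 with a common UMI minimum and 0.30 with each library clustered alone), and with the doubtful clusters left out the neutrophil folds of Thbs1 and Ccl3 were −1.001 and −1.37, while a common UMI minimum gave monocyte folds of 0.79 for F11r (0.84 with doublets kept) and 4.005 for Saa3. With a 500 UMI minimum the folds were 3.87 for Saa3 and, in neutrophils, 1.87 for Stfa2 and 1.85 for Wfdc17, the ratios were 0.676 for B cells, 0.643 for monocytes, 0.686 for natural killer cells, 0.269 for T cells, 0.224 for plasma cells, 0.154 for type 1 and 0.110 for type 2 dendritic cells, and with each library clustered alone they were 3.76 for Kupffer cells and 0.0703 for monocyte-derived macrophages, whose interferon median was −0.01 with a 10% mitochondrial limit. Across the alternatives the highest ratios were 0.808 for T cells, 0.817 for plasma cells, 2.02 for monocytes and 2.24 for natural killer cells. For type 1 and type 2 dendritic cells they were 0.519 and 0.304. The lower T and plasma cell shares therefore did not stay past 1.5-fold under each alternative.

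The salted Western diet, compared with chow, held larger shares of monocytes, Kupffer cells and monocyte-derived macrophages and smaller shares of plasma and T cells. This pair sets the combined diet beside the control. Monocytes had a ratio of 2.34 (2.20 to 2.49), Kupffer cells of 2.82 (2.54 to 3.13), monocyte-derived macrophages of 1.52 (1.39 to 1.66) and neutrophils of 1.24 (1.17 to 1.31). The gamma-delta T or innate lymphoid class stood at 0.932% against 0.261%, a ratio of 3.58 (2.46 to 5.20). Plasma cells had a ratio of 0.133 (0.117 to 0.151), T cells of 0.540 (0.511 to 0.571), B cells of 0.886 (0.848 to 0.925), natural killer cells of 1.37 (1.16 to 1.61), plasmacytoid dendritic cells of 0.871 (0.673 to 1.13), and type 1 and type 2 dendritic cells of 0.701 (0.645 to 0.763) and 0.647 (0.594 to 0.705).

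The inflammatory list had medians of 0.15 in monocytes, with no measured member past 1.5-fold, and −0.14 in Kupffer cells, with 2 of 8 measured members higher and 2 lower by at least 1.5-fold, and stood at 0.34 in monocyte-derived macrophages and 0.48 in neutrophils. The interferon list was higher in neutrophils by 0.75 with 10 of 12 members at least 1.5-fold higher, in plasmacytoid dendritic cells by 0.92 and in Kupffer cells by 0.64. Neutrophils had higher Ltc4s (2.05), the leukotriene C4 synthase, Slfn5 (1.57) and Ifit3 (1.496), and lower Camp (−3.61), Ngp (−3.55) and the ficolin Fcnb (−3.30), and their proliferation list was at −1.28. Kupffer cells had a proliferation median of 1.00 and a resident median of 0.27, and monocyte-derived macrophages a lipid-associated median of 0.46 with Gpnmb at 1.76 and Spp1 at 1.45. Cluster 34, high in proliferation markers, held 8.17% of the Kupffer cells (151 cells) on the salted Western diet and 0.985% (4 cells) on chow. In monocytes Saa3 (1.84), Tppp3 (0.86) and Clec4e (0.75) were higher, and Dusp1 (−1.41), Lyz1 (−1.34) and the fatty acid receptor Cd36 (−1.27) lower. T cells had higher Ccl3 (1.87), Ccl4 (1.56) and Klra9 (1.17) and lower S1pr5 (−1.65) and Il18rap (−1.29), and B cells had higher Cr2 (0.58) and Cd40 (0.43) and lower Cxcr4 (−0.87) and Zfp36l2 (−0.87). Of these B cells 94.0% lay in cluster 4 on the salted Western diet and 90.7% in cluster 9 on chow. In the empty barcodes Alb, Apoa1, Ttr and Mup3 had ratios of 1.16, 0.198, 2.36 and 0.169, and the urea cycle list had a median of −0.03, de novo lipogenesis 0.18, cholesterol synthesis 0.04, fatty acid oxidation 0.23, the acute phase list −0.55 and the pericentral list 0.04 with a mean of −0.09. With each library clustered alone the ratios were 8.04 for Kupffer cells and 1.59 for plasmacytoid dendritic cells, and a common UMI minimum gave 2.66 for monocyte-derived macrophages. The proliferation medians were −0.25 in the Clec4f-led Kupffer cluster and −0.36 in neutrophils without the cluster led by Ngp, Ltf and Camp, where Fcnb was at −0.28, Camp at −2.70 and Ngp at −2.52 (−0.31, −2.38 and −2.63 with each library clustered alone), and the monocyte folds were −0.18 for Cd36 at resolution 0.5 and, for Saa3, 1.14 at 500 UMIs, 1.08 at 1000 UMIs and 1.13 with doublets kept.

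The difference between salt on the Western diet and salt on chow sets the first of these pairs against the third. In monocytes the inflammatory list differed by −1.18, the log2 fold on the Western diet minus that on chow, in monocyte-derived macrophages by −1.11, in neutrophils by −0.67 and in Kupffer cells by 0.01. Interferon genes differed by 0.88 in plasmacytoid dendritic cells, 0.79 in natural killer cells, 0.70 in neutrophils, 0.39 in monocytes, 0.34 and −0.18 in type 1 and type 2 dendritic cells, 0.31 in T cells, −0.13 in monocyte-derived macrophages, 0.01 in Kupffer cells and 0.02 in both B and plasma cells. The resident list in Kupffer cells differed by −0.89 and antigen presentation by 0.70 there and 0.92 in plasmacytoid dendritic cells, and proliferation in neutrophils by 1.11. In T cells the IL-17 axis list differed by 0.29. These differences depend on the processing. On the Western diet the inflammatory median of monocyte-derived macrophages was 0.17 and that of Kupffer cells 1.10 with free RNA subtracted, and on chow the Kupffer medians were 0.20 for antigen presentation and 0.52 for the resident list in the Clec4f-led cluster. Under trimmed means the neutrophil medians on the Western diet and on chow were 0.29 and 0.24 for interferon, 0.30 and −0.15 for proliferation, and −1.92 and −0.63 for the inflammatory list. These differences have no test, since each is built from 4 single libraries.

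**Figure D3:**
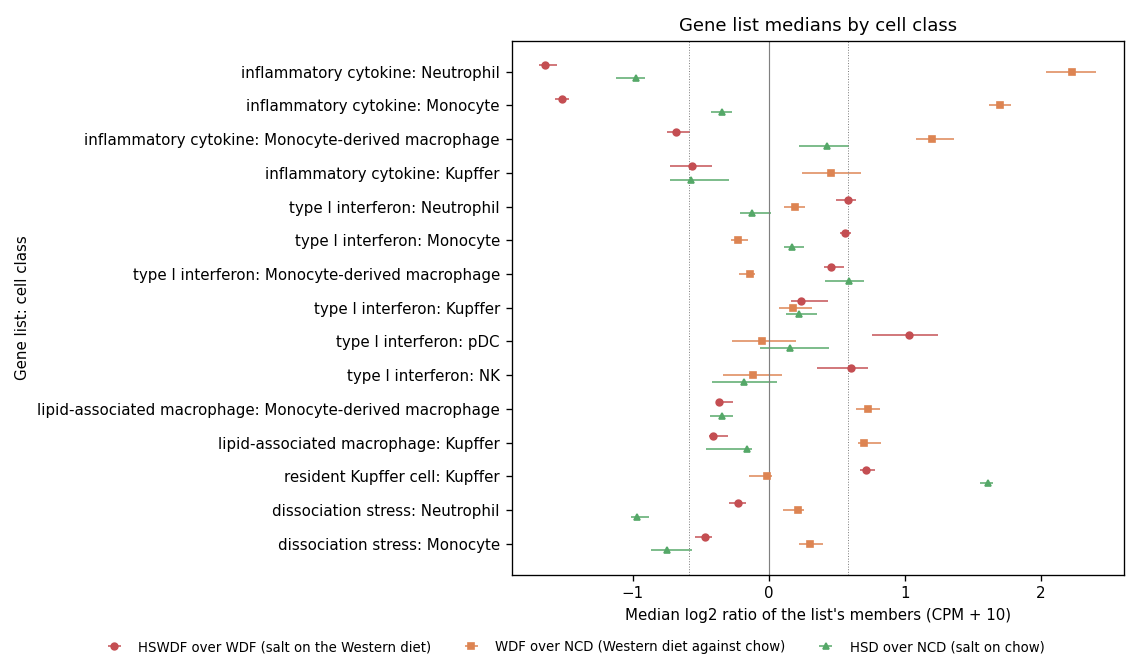
Median log2 fold of fixed gene lists (horizontal axis, CPM plus 10) in named cell classes for the 3 pairs drawn; each point is 1 list in 1 class, and bars are 95% intervals for counting error. The inflammatory list in neutrophils stood at −1.65 for salt on the Western diet, 2.23 for the Western diet against chow and −0.98 for salt on chow.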

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

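The tests in this part were chosen after the results they address were seen. The explanations left open below are open for this set of 4 libraries alone.

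Salt went with opposite changes on the 2 diets, past 1.5-fold on each, for 3 immune classes. The neutrophil share ratio was 0.644 for salt on the Western diet and 2.41 for salt on chow, that of type 1 dendritic cells 2.03 and 0.312, and that of the gamma-delta T or innate lymphoid class 4.70 and 0.502. With the doubtful clusters left out the neutrophil ratio on the Western diet was 1.19. That setting removes cluster 8, which held 60.0% of the neutrophils without salt and 12.5% with it. It therefore cannot decide whether the opposition in that class is real. Plasmacytoid dendritic cells (1.45 and 0.401), plasma cells (1.35 and 0.491) and monocytes (0.800 and 1.21) also went opposite ways, by less than 1.5-fold on at least 1 diet, but at resolution 2 the plasmacytoid ratio on the Western diet was 0.976, and with a 500 UMI minimum the monocyte ratio on chow was 0.643. The gamma-delta T or innate lymphoid ratios have no value under the alternatives. The difference between the diets was not tested, since each diet has 1 library.

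Unnamed clusters outside the comparisons were larger in another library than in the chow library. Cluster 21, led by the granule genes Mpo, Elane, Ctsg and Prtn3 of myeloid progenitors, held 3.27% of all cells on salted chow and 1.16% on chow. Cluster 23, led by Clu, Spp1 and genes that include the hepatocyte genes Alb and Ttr, held 3.08% on the salted Western diet and 0.504% on chow. Cluster 27, with the platelet genes Pf4 and Ppbp beside the neutrophil genes Ltf and Ngp, held 2.43% on salted chow and 0.194% on chow. None of these differences was tested.

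The first pattern weighed is the lower inflammatory RNA on the salted Western diet. Free RNA is argued against in neutrophils, where the 11 measured members stood above the empty barcodes of the Western diet library by a median of 5.87-fold (2.47 to 8.09 across members), and in monocytes, whose median stayed at −1.43 after subtraction by neutrophil markers and at −1.42 by secreted-protein genes, but not in monocyte-derived macrophages, where the subtractions gave −0.52 and 0.17, nor in Kupffer cells, where the second gave 1.10. The share taken off Kupffer cells was at its limit of 50% without salt and at 14.9% with it, so that value cannot decide. Handling that moves the dissociation list is argued against as the whole cause in neutrophils, where that list was at −0.23 against −1.65 for the inflammatory list, and at −0.08 against −0.55 with the doubtful clusters left out, 1 of which held 60.0% of the neutrophils without salt. The cluster led by Ngp, Ltf and Camp held 0.207% of the neutrophils without salt and 0.849% with it, and the median was −1.63 without that cluster. These cells were too few to move the median, so leaving them out was no test of immature neutrophils. Immature neutrophils in other clusters were not tested and stay open. An effect of the salted diet, a difference between single mice and handling that leaves the dissociation list alone may each account for what remains.

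The second pattern is the higher Kupffer share with salt on each diet. Fewer cells of 1 other class alone would leave the remaining classes with the ratio of Kupffer cells, yet the second lowest ratio was 0.644 on the Western diet (neutrophils) and 0.261 on chow (monocyte-derived macrophages). On the Western diet the ratio of the gamma-delta T or innate lymphoid class, 4.70 (3.29 to 6.71), overlapped that of Kupffer cells, 6.01 (5.31 to 6.81), and on chow that of neutrophils was higher than the Kupffer ratio, at 2.41 against 1.81. Counting the C1q-led cluster as monocyte-derived macrophages left Kupffer ratios of 8.11 on the Western diet and 3.60 on chow, and 1 common UMI minimum left ratios of 5.57 and 3.18. Unequal losses of several classes, or a different yield of Kupffer cells, in the dissociation or the spin cannot be told apart from an effect of salt, because there was 1 library per diet. A larger or better-retained Kupffer population with salt may also be the cause, and no test here separates these.

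The third pattern is the higher interferon list in monocytes on the salted Western diet. Free RNA is argued against, since the median was 0.64 after subtraction by neutrophil markers and 0.59 by secreted-protein genes. The cluster led by Ifit2 held 0.879% of the monocytes without salt and 1.75% with it. The median was 0.52 without the 200 cells of that cluster in the 4 libraries. That cluster alone did not make the difference, but strongly responding cells in other clusters were not examined and stay open. An interferon response tied to the salted diet, or an infection or other state of the mice in that library, may account for the higher list, and 1 library per diet leaves these open.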

How the results depend on the processing

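Of the alternatives, 18 were planned and 6 were chosen after seeing the data (shares without neutrophils and B cells, the C1q-led cluster moved to monocyte-derived macrophages, no doubtful clusters, lists without class markers, the Clec4f-led cluster alone, and no cluster led by Ngp, Ltf and Camp). Over the 557 values of 44 share ratios, 22 changed direction (3 from ratios past 1.5-fold, called turned below) and 185 moved beyond counting error, and 318 of 367 values of ratios past 1.5-fold stayed past it. Over the 7601 values of 443 list medians, 600 changed direction (14 from medians past 1.5-fold) and 1525 moved, and 603 of 710 values of medians past 1.5-fold stayed past it. Over the 1554 values of 96 named genes, none changed direction and 423 moved, and 1428 of 1442 past 1.5-fold stayed past it. These genes were picked for the most extreme folds in the same data, so a kept direction was close to given.

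The results that answer the comparisons kept their direction under each alternative that gave a value. Kupffer ratios ranged from 4.33 to 9.98 for salt on the Western diet and from 2.76 to 8.04 for the salted Western diet over chow, the macrophage ratio (monocyte-derived, Western diet over chow) from 1.52 to 8.48, the neutrophil ratio (salt on chow) from 2.24 to 3.40 and the B cell ratio (salt on the Western diet) from 2.48 to 2.93. The neutrophil inflammatory median ranged from −1.92 to −0.55 for salt on the Western diet and from 0.59 to 2.75 for the Western diet over chow, and the monocyte interferon median (salt on the Western diet) from 0.47 to 0.66. The lipid-associated median (monocyte-derived macrophages, Western diet over chow) ranged from 0.27 to 1.08 and the resident median (Kupffer cells, salt on chow) from 0.48 to 2.00. Values outside the counting interval follow, for these pairs, and the cause was not tested.

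With a 500 UMI minimum the Kupffer ratio on the Western diet was 7.46, the macrophage ratio 2.53, the neutrophil ratio 3.40 and the resident median 0.51. With 1000 UMIs the macrophage ratio was 2.71, the lipid-associated median 1.01 and the resident median 1.498. A common minimum gave a Kupffer ratio over chow of 3.15, a macrophage ratio of 3.65, and medians of 0.47 (interferon), 0.47 (lipid-associated) and 0.69 (resident). A 10% mitochondrial limit gave a Kupffer ratio on the Western diet of 4.33, and no limit gave 5.07, a macrophage ratio of 7.91 and a neutrophil ratio of 2.29. With doublets kept the macrophage ratio was 5.45, and the medians were −1.74 (inflammatory, salt on the Western diet), 0.58 (lipid-associated) and 1.55 (resident).

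At resolution 0.5 the Kupffer ratio on the Western diet was 6.87, the macrophage ratio 2.55 and the resident median 1.41. At resolution 2 the macrophage ratio was 8.48, the neutrophil ratio 2.24, the lipid-associated median 0.27 and the resident median 1.55, and the plasmacytoid dendritic cell ratio of the Western diet over chow turned to 1.00. Clustering each library alone gave Kupffer ratios of 9.98 on the Western diet and 8.04 over chow, a macrophage ratio of 1.52, a B cell ratio of 2.73, and medians of −1.70 (inflammatory, salt on the Western diet), 0.62 (interferon), 1.08 (lipid-associated) and 0.52 (resident). Moving the C1q-led cluster gave a Kupffer ratio of 8.11 on the Western diet, a macrophage ratio of 2.46, a lipid-associated median of 0.62 and a resident median of 0.50. Leaving out the doubtful clusters gave a Kupffer ratio of 5.12 on the Western diet, a macrophage ratio of 3.79, a B cell ratio of 2.48, inflammatory medians of −0.55 (salt on the Western diet) and 0.59 (Western diet over chow) and an interferon median of 0.51, and it turned the neutrophil ratios to 1.19 (salt on the Western diet) and 0.994 (Western diet over chow), since it removes the cluster that held most Western diet neutrophils.

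Subtracting free RNA gave inflammatory medians of −1.82 (salt on the Western diet) and 2.43 (Western diet over chow), 0.94 for the lipid-associated list and 2.00 for the resident list. The share taken off was at its limit of 50% in neutrophils on the Western diet and in Kupffer cells on salted chow. Trimmed-mean scaling gave −1.92 (inflammatory, salt on the Western diet), 0.49 (interferon) and 1.67 (resident). A pseudocount of 1 gave −1.76 and 2.75 for the inflammatory list in the same order of pairs and 0.66 for interferon. Lists of members with 1 UMI gave inflammatory medians of −1.54 and 2.02. For the Western diet over chow the inflammatory median was 2.45 with members at 50 CPM, 1.89 as a mean over cells and 1.88 without the cluster led by Ngp, Ltf and Camp. The resident median was 1.32 as a mean over cells, 0.48 without class markers and 0.52 in the Clec4f-led cluster alone.

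Other list medians past 1.5-fold that turned were, in monocyte-derived macrophages, inflammatory (0.17, free RNA subtracted, salt on the Western diet), interferon (−0.01, 10% mitochondrial limit, salt on chow) and resident (Western diet over chow, −0.87 at 500 UMIs, −1.42 with a common minimum, −0.83 clustered alone and −0.38 with the C1q-led cluster). In Kupffer cells they were proliferation in the Clec4f-led cluster (−0.29 and −0.25 for the 2 Western diets over chow) and antigen presentation on salted chow (0.01 with a common minimum, 0.30 clustered alone, 0.17 with the C1q-led cluster moved, 0.20 in the Clec4f-led cluster). The last were NRF2 in neutrophils on salted chow (0.03 without the doubtful clusters) and the acute phase (0.81 at 50 CPM, Western diet over chow). Counting error was wide in small classes, as with 27 to 185 gamma-delta T or innate lymphoid cells. There was no ratio for plasmacytoid dendritic cells at 500 UMIs, nor, clustered alone, for them on salted chow or for monocyte-derived macrophages on the salted Western diet. Kupffer cells thinned to 1000 UMIs had medians of 655, 673.5, 671 and 653 genes for chow, salted chow, the Western diet and the salted Western diet.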

Other observations

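Beyond the comparisons, an unnamed cluster of 962 cells carried a myeloid progenitor profile, with Mpo at 3560 CPM and Elane at 3566 CPM, the granule proteases that developing granulocytes make. It held 1.16% of all cells on chow, 3.27% on salted chow, 0.175% on the Western diet and 0.275% on the salted Western diet. A cluster of 808 cells had Clu at 25450 CPM, Spp1 at 22553 CPM, the epithelial adhesion gene Epcam at 839 CPM, the duct keratin Krt19 at 330 CPM and Sox9, a transcription factor of duct cells, at 192 CPM. It held 0.504% of all cells on chow, 0.411% on salted chow, 0.0822% on the Western diet and 3.08% on the salted Western diet. Albumin was among its leading genes as well, so it was not given a class.

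A cluster of 571 cells carried the platelet chemokine Pf4 at 1812 CPM together with neutrophil granule genes. It held 0.194% of all cells on chow, 2.43% on salted chow, 0.0110% on the Western diet and 0.0338% on the salted Western diet. Unnamed cells of all kinds made up 2.16%, 6.46%, 0.367% and 3.59% of cells on chow, salted chow, the Western diet and the salted Western diet.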
